A study of Mus musculus with 6 samples.

How the data were processed

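RNA was sequenced from primary airway basal cells of wild-type mouse tracheas after 4 days of culture, with 3 libraries of cells given UK-5099 and 3 of cells given Y-27632, A8301 and DMH-1. Per the labels, libraries were made with the VAHTS Universal V8 kit from 1 to 1.5 µg of total RNA. The submitters' processing notes name HISAT2 2.1.0, DESeq2 1.36.0 and the genome build GRCm39, without stating the role of each, and the tool that counted reads and the gene annotation are not given in the sources used here. The deposited table holds values in a unit other than plain counts, namely the log2 of gene read counts that the authors had divided by a size factor per library, with a text mark where the count was 0.

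The deposited values were raised back from log2 to normalized counts, with the text mark read as 0. The table had 57107 entries, of which 359 repeated a gene identifier, leaving 56748 genes, and 25708 of these were 0 in every library. Every library's values were whole multiples of 1 step, the worth of a single read, so reads were recovered by division. Between 99.988% and 99.992% of the nonzero values per library lay within 0.02 of a whole number of reads. Recovered reads per library ranged from 19909589 to 27037795. Of 2693 genes without a symbol in the table, 43 were given one from a reference table by identifier. No coordinates were used, because the reference at hand was for another genome build.

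Genes with a mean of at least 10 normalized counts over the 6 libraries were tested, 15704 in all. The log2 of the normalized count plus 1 was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, two-sided), without covariates, and p values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The plan, fixed before the data were examined, held a branch for raw counts and a branch for normalized or log values, and the latter was used because the table holds no raw counts. Log2 fold changes are UK-5099 minus 3 inhibitors, and folds are powers of 2 of these. Errors of normalized counts are SD over 3 libraries, and those of log2 fold changes are the standard errors of the fit. The median standard error was 0.0858.

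Before the data were examined, 44 gene lists were fixed from general knowledge. The 36 with at least 5 tested members were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists. The same test with an estimated correlation and fry were run beside it. Named genes followed a rule fixed at the same time. It took the 12 genes with the largest rise and the 12 with the largest fall among called genes whose replicates did not overlap between groups, whose mean was in the top 50% of the genes tested and whose symbol was not a placeholder. It also took up to 4 called members of each list by smallest adjusted p, and a set of receptor, carrier and marker genes whatever their result. The results of a few of these genes are not reported. Sex-linked genes and the families described in the closing section were chosen after their values were seen. The share of normalized counts from the 13 protein genes of the mitochondrial genome was compared by an exact permutation test, for which 0.1 is the smallest p with 3 against 3.

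The steps were tested on simulated data with 200 changed genes among 15531, 50 at each fold. They recovered 64% of genes changed 1.25-fold, 78% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and 13 unchanged genes made up 7.1% of the calls. In the data 53.8% of the genes tested were called, and the simulation held no error of scaling, so these percentages need not hold there. A list shifted by 0.5 on the log2 scale was called and 0 of 34 unchanged lists were. Genes were simulated independently of each other, whereas the estimated inter-gene correlation in the data had a median of 0.265 over the lists. The simulation therefore does not test list calls where members are correlated.

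Alternatives were upper-quartile rescaling, centring on the median, no low filter, a minimum mean of 50, limma without the trend or with robust estimation, pseudocounts of 0.5 and 5, a change of at least 2-fold, a threshold of 0.01, the replicate number as a block, and each library left out in turn. Fits of limma-voom to the recovered reads were added after the data had been seen. Scripts ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.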

Results

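Gene expression was measured by RNA sequencing in primary airway basal cells of wild-type mouse tracheas, the stem cells of the airway epithelium, after 4 days of culture with small-molecule inhibitors. There were 6 libraries in 2 groups. Cells of 3 libraries had received UK-5099, an inhibitor of the mitochondrial pyruvate carrier, through which pyruvate enters the mitochondrial matrix. Cells of the other 3 libraries had received 3 inhibitors together: Y-27632, A8301, which blocks TGF-beta type I receptors, and DMH-1, which blocks BMP type I receptors. A8301 and DMH-1 are the pair known as dual SMAD inhibition. No untreated group was among the samples, so each difference is one between the inhibitor conditions and does not say which of them moved. The labels name no other component of the medium and do not state whether the UK-5099 cultures also held Y-27632. The deposited values corresponded to 23739915, 25663880 and 19909589 gene reads in UK-5099 replicates 1, 2 and 3, and to 23710133, 27037795 and 25985542 in 3-inhibitor replicates 1, 2 and 3. The labels do not state that the replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

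The comparison asked how basal cells expanded with UK-5099 differed from basal cells expanded with the 3 inhibitors. With UK-5099, 27 of 32 genes of squamous differentiation and all 35 genes of mitosis were higher, whereas 16 of 21 genes of airway secretory cells and 20 of 24 genes of glycolysis were lower. Each of these lists passed the camera test (adjusted p from 1.51e-17 to 4.02e-06), and none did with an estimated correlation (adjusted p = 0.385 for each). The adjustment over the lists gave this same lowest value to several lists, here and below, so it does not tell them apart. Krt5, the keratin that marks airway basal cells, stood at 118700 ± 7085 normalized counts with UK-5099 and 39450 ± 2455 with the 3 inhibitors (SD, n = 3 each), a log2 fold change of 1.59 ± 0.06 (SE). Muc1, a membrane mucin of secretory cells, stood at 39.7 ± 15.4 and 1115 ± 46.9 normalized counts. Of 15704 genes tested, 8449 differed at a Benjamini-Hochberg adjusted p under 0.05 (limma), 4275 of them higher and 4174 lower with UK-5099. Most of these differences were small: 5047 were under 1.5-fold, and 1593 genes differed by at least 2-fold, 733 higher and 860 lower. The share of called genes that were higher was 50.6%. It was 39.1% when each library was centred on the median of the genes tested and 54.5% after upper-quartile rescaling. Values of the replicates did not overlap between the groups for 9543 genes, 60.8% of those tested, against 10% by chance for 3 against 3. The first principal component held 76.6% of the variance and separated the groups.

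Genes of the X and Y chromosomes, singled out after their values were seen, also differed between the groups. Xist, the RNA that silences an X chromosome in female cells, was 1.70-fold higher with UK-5099 (24280 ± 1528 against 14250 ± 129 normalized counts, SD, n = 3). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were 1.76-fold, 1.88-fold, 2.15-fold and 1.52-fold lower with UK-5099. In all 6 libraries both Xist and the Y-linked genes were expressed, and the labels do not state the sex of the animals. This difference ran alongside every gene group described here.

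The 12 genes with the largest higher values under the fixed rule were led by Krt16, a keratin of stressed and squamous epithelium, with 10470 ± 195 against 568 ± 47.3 normalized counts (SD, n = 3; log2 fold change 4.20 ± 0.06, SE). Spink5, an inhibitor of epidermal proteases, was 13.5-fold higher, Ly6d and Ly6g6c were each 13.4-fold higher, and Sparc, a matrix protein, was 12.1-fold higher. The desmosomal cadherin Dsc3 was 11.6-fold higher and the connexin Gjb2 11.2-fold higher. Krt6b and Sprr2a3 were 11.2-fold and 10.8-fold higher, and Pi15, Dmkn and the tubulin Tubb3 completed the set with log2 fold changes of 3.38, 2.93 and 2.86. Krt6a, Krt6b and Sprr2a3 have near-identical copies with which reads can be shared, so their levels are uncertain. At the other end, Cp, which encodes the copper-carrying plasma protein ceruloplasmin, was 16.8-fold lower with UK-5099 and the mucin Muc4 was 12.8-fold lower. The chemokine gene Cxcl5 was 9.28-fold lower. Atp1b1, a subunit of the sodium-potassium pump, fell from 14400 ± 272 normalized counts with the 3 inhibitors to 1695 ± 24.7 with UK-5099, and Slc4a4, a sodium bicarbonate cotransporter, was 8.01-fold lower. Tc2n, Prkaa2 (a catalytic subunit of AMP-activated kinase), Clu, Npnt, Celf2 and the water channel Aqp4 were between 7.12-fold and 7.73-fold lower. The adjusted p of the 24 genes chosen by this rule, Muc1 included, ranged from 1.08e-12 to 2.53e-08.

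**Figure D1:**
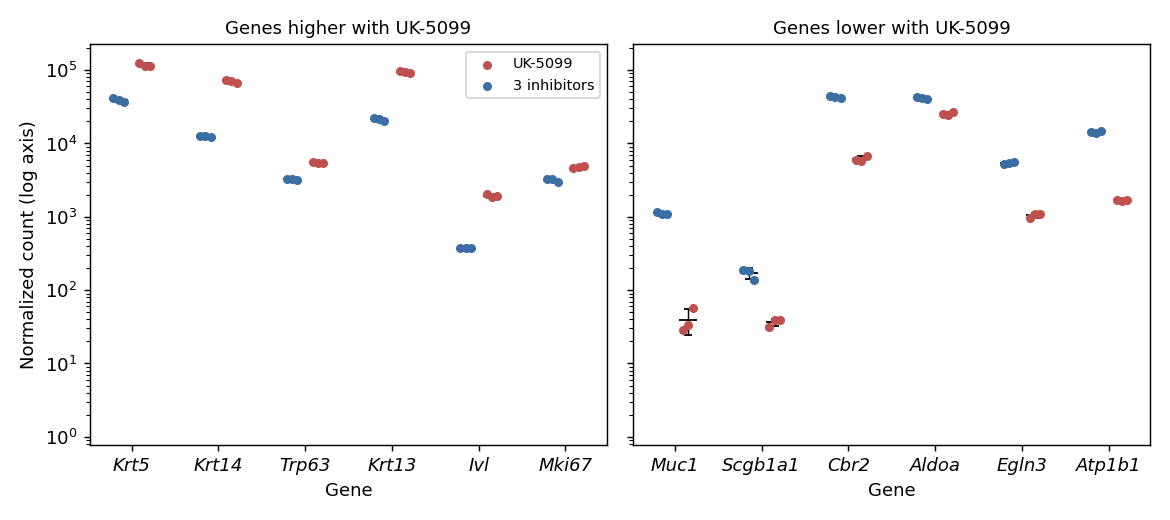
Normalized counts (log axis) of 12 genes in each of the 6 libraries, with 3 libraries per group; coloured points are libraries, horizontal marks are group means and error bars are SD, mostly hidden by the points. Krt5, Krt14, Trp63, Krt13, Ivl and Mki67 are higher in every UK-5099 library, and Muc1, Scgb1a1, Cbr2, Aldoa, Egln3 and Atp1b1 are lower in every one.

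Most listed genes of airway basal cells and of squamous differentiation were higher with UK-5099. Of 20 basal cell genes, 15 were higher, 3 lower and 2 did not pass the test, with a median log2 fold change of 0.65 (camera, adjusted p = 3.33e-05, and adjusted p = 0.450 with an estimated correlation). Krt14 was 5.66-fold higher (70520 ± 3764 against 12460 ± 236 normalized counts, SD, n = 3), Krt17 was 3.26-fold higher, and Trp63, the transcription factor that maintains basal cells, was 1.70-fold higher. Perp, a desmosomal protein, was 1.89-fold higher. The 3 lower, chosen after their values were seen, were the basal cell marker Ngfr (log2 fold change -2.20 ± 0.16, 65.9 ± 12.8 against 304.0 ± 42.9 normalized counts), Aqp3 (-0.43) and Cav1 (-0.20). Of 32 genes of squamous and hillock cells, the stratified squamous-like cells of the airway, 27 were higher and 2 lower, 22 of the former by at least 2-fold (camera, adjusted p = 2.96e-12, and adjusted p = 0.385 with an estimated correlation). Krt13, a hillock keratin, stood at 94230 ± 1966 normalized counts with UK-5099 and 21620 ± 1047 with the 3 inhibitors. Other hillock genes, chosen after their values were seen, did not rise alike. Krt4 and Ecm1 had log2 fold changes of only 0.22 and 0.28. Lgals3 was lower (-0.71 ± 0.05, 35340 ± 2160 against 57540 ± 594 normalized counts), and the other lower gene of the list was Lor (-0.87). Ivl, which encodes the cornified envelope protein involucrin, was 5.11-fold higher, and Krt6a was 5.58-fold higher.

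Secretory cell genes were lower with UK-5099: of 21 tested, 16 were lower, 12 of them by at least 2-fold, and 2 were higher (median log2 fold change -1.49; camera, adjusted p = 4.02e-06, and adjusted p = 0.385 with an estimated correlation). Cbr2, a carbonyl reductase abundant in club cells, stood at 6150 ± 611 normalized counts with UK-5099 and 42900 ± 1197 with the 3 inhibitors. Lypd2 was 3.40-fold lower. Scgb1a1, the main secreted protein of club cells, was low in both groups, at 36.5 ± 4.32 and 170.9 ± 27.9 normalized counts. Few multiciliated cell genes were detected. Only 11 of 36 passed the low filter, of which Rsph1 and Cfap43 were higher and Rsph9 and Myb lower (camera, adjusted p = 0.67), and Foxj1, the master regulator of these cells, was below the filter at 0.339 and 3.23 normalized counts. The calls of Rsph9 and Myb ended when 3-inhibitor replicate 1 was left out (adjusted p = 0.0645 and 0.0957), and that of Myb also without UK-5099 replicate 1 (adjusted p = 0.0589). Over all alternatives their adjusted p ran from 0.00494 to 0.0645 for Rsph9 and from 0.0111 to 0.0957 for Myb.

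Genes of other cell types were mostly at the floor. Among ionocyte genes 3 of 10 were tested, of which Atp6v1c2 was higher and Cftr and P2ry14 lower. Of tuft cell genes 3 of 14 were tested, with Sh2d6 higher and Avil and Dclk1 lower. The calls of P2ry14 and Dclk1 were each lost in 4 of the 6 fits that left out a library and in other settings, with adjusted p from 0.0275 to 0.152 for P2ry14 and from 0.00780 to 0.136 for Dclk1. For P2ry14 these were the fits without UK-5099 replicate 3 or any 3-inhibitor replicate, and for Dclk1 those without UK-5099 replicate 1 or 2 or 3-inhibitor replicate 2 or 3. Insm1 was the 1 neuroendocrine gene tested, at 3.70 ± 3.25 normalized counts with UK-5099 and 19.9 ± 11.2 with the 3 inhibitors. Fbln1 was the 1 fibroblast gene tested of 15 and was 1.59-fold higher. Col2a1 was higher and Col11a2 lower among 13 cartilage genes, and Notch3 was higher and Ckb lower among 11 genes of smooth muscle and pericytes. Endothelial genes had a median log2 fold change of 0.08 but a mean of -0.60, with Tie1 and Vwf lower among 5 tested (camera, adjusted p = 0.453). Of 3 leukocyte genes tested, Cd74 was lower, at 6.60 ± 1.32 against 27.7 ± 6.64 normalized counts. Among glial and neuronal genes Tubb3 was higher and Mbp was 2.50-fold lower.

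Cell cycle genes were higher with UK-5099. All 35 tested genes of G2/M phase and mitosis were higher, with a median of 1.95-fold (camera, adjusted p = 1.51e-17, and adjusted p = 0.385 with an estimated correlation), including Tpx2 (2.23-fold), Top2a (2.18-fold), Cdc20 (2.17-fold) and Hmmr (2.34-fold). Mki67, the proliferation marker, was 1.50-fold higher, at 4769 ± 106 against 3184 ± 140 normalized counts (SD, n = 3). Of 34 genes of S phase and DNA replication, 31 were higher and none lower (camera, adjusted p = 2.17e-12, and adjusted p = 0.385 with an estimated correlation). The ribonucleotide reductase genes Rrm1 and Rrm2 were 2.04-fold and 2.12-fold higher, Mcm4 1.90-fold and Pola1 2.16-fold. Genes of MYC and ribosome biogenesis were higher in 26 of 28 cases, with none lower (camera, adjusted p = 2.05e-09, and adjusted p = 0.385 with an estimated correlation). Odc1, the first enzyme of polyamine synthesis, was 2.02-fold higher, and Dkc1, Cad and Mybbp1a had log2 fold changes of 0.68, 0.60 and 0.46. Targets of p53 and cell cycle inhibitors were mixed, with 7 of 27 higher and 11 lower (camera, adjusted p = 0.453). Among them Cdkn1a was 1.50-fold lower, Trp53inp1 1.41-fold lower and Gdf15 2.14-fold lower, whereas Cdkn2a was 4.18-fold higher.

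The carrier that UK-5099 inhibits is built of Mpc1 and Mpc2. Mpc1 stood at 362 ± 13.2 normalized counts with UK-5099 and 425.8 ± 16.02 with the 3 inhibitors (log2 fold change -0.23 ± 0.07, adjusted p = 0.0165), and its call ended without UK-5099 replicate 1 (adjusted p = 0.0595) and without 3-inhibitor replicate 1 (adjusted p = 0.0703), in a range over all alternatives from 0.00232 to 0.0703. Mpc2 did not pass the test (-0.04 ± 0.06, adjusted p = 0.550). Around the carrier, 8 of 14 genes of mitochondrial pyruvate entry were lower and 2 higher (camera, adjusted p = 0.0924, or 0.0400 without the low filter, in a range from 0.0400 to 0.131 with the preset correlation; adjusted p = 0.385 with an estimated correlation and 0.000398 by fry). Pcx, which makes oxaloacetate from pyruvate, was 1.98-fold lower, and the pyruvate dehydrogenase kinases Pdk1 and Pdk2 were 1.34-fold and 1.92-fold lower, with Pdp1, the opposing phosphatase, 1.49-fold lower.

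Glycolysis genes were lower with UK-5099 in 20 of 24 cases and higher in none (camera, adjusted p = 5.86e-07, and adjusted p = 0.385 with an estimated correlation). Aldoa stood at 25440 ± 1577 against 42080 ± 1228 normalized counts, Gpi1 was 1.65-fold lower, Pfkp 1.69-fold and Ldhb 3.72-fold lower. Of 25 targets of HIF1, the transcription factor of the response to low oxygen, 22 were lower and 3 higher (camera, adjusted p = 4.31e-07, and adjusted p = 0.385 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, was 5.10-fold lower, P4ha2 3.62-fold, Ak4 2.09-fold and Kdm3a 1.92-fold lower. In the pentose phosphate pathway, which yields NADPH and ribose, 8 of 9 genes were higher (camera, adjusted p = 0.000864, and adjusted p = 0.385 with an estimated correlation), with a log2 fold change of 0.44 for G6pdx, and by 1.37-fold for Taldo1, 1.47-fold for Prps1 and 1.54-fold for Prps2.

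Respiratory chain genes encoded in the mitochondrial genome were lower with UK-5099, 10 of 13 with none higher (camera, adjusted p = 0.000123, and adjusted p = 0.458 with an estimated correlation). mt-Nd5, mt-Cytb, mt-Nd2 and mt-Nd4l were 1.49-fold, 1.47-fold, 1.40-fold and 1.38-fold lower. These 13 genes made up 3.55 ± 0.10% of all normalized counts with UK-5099 and 4.31 ± 0.14% with the 3 inhibitors (SD, n = 3; exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 can give). Nuclear-encoded genes of oxidative phosphorylation differed little: 31 of 73 were higher and 8 lower, with a median of 1.09-fold (camera, adjusted p = 0.0173, and adjusted p = 0.752 with an estimated correlation). Ndufa4 and Atp5g1 had log2 fold changes of 0.71 and 0.42, and Cox7a2l and Cox4i1 of -0.41 and -0.31. The call of this list ended when libraries were centred on their median, where the list's median log2 fold change was 0.04 against 0.13 (adjusted p = 0.160), and without UK-5099 replicate 1 (median 0.11, adjusted p = 0.0513), in a range with the preset correlation from 0.000553 to 0.160, and by fry (adjusted p = 0.0692). Citric acid cycle genes were mixed, with 4 of 20 higher and 7 lower (median log2 fold change 0.01, mean -0.04; camera, adjusted p = 0.524). Idh3a, Idh2, Sdha and Aco1 had log2 fold changes of -0.50, -0.39, -0.25 and -0.23.

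Lipid and amino acid genes moved in part. Cholesterol synthesis genes were higher in 16 of 25 cases with none lower (camera, adjusted p = 0.000715, and adjusted p = 0.610 with an estimated correlation), led by Dhcr7 at 1.99-fold, with Pmvk at 1.53-fold, Acat2 at 1.38-fold and Idi1 at 1.37-fold. Fatty acid synthesis genes were higher in 9 of 17 cases and lower in 5 (camera, adjusted p = 0.304). Acss2, which makes acetyl-CoA from acetate, was 2.73-fold higher, Fads2 and Acaca were 1.38-fold and 1.32-fold higher, and Scd1 was 1.42-fold lower. Fatty acid oxidation and PPAR target genes had 7 higher and 10 lower of 32 (camera, adjusted p = 0.385). Ppargc1a, a coactivator that promotes mitochondrial gene expression, was 2.51-fold lower and Cd36 3.16-fold lower, whereas Ppard was 2.28-fold and Ucp2 2.18-fold higher. Of 24 genes of glutamine and amino acid use, 9 were higher and 8 lower (camera, adjusted p = 0.871), with Oat, Pycr1 and Slc6a14 higher and Glul 1.96-fold lower.

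The receptors that A8301 and DMH-1 block and the genes downstream of them did not move as one. The TGF-beta type I receptor gene Tgfbr1 was 1.49-fold lower with UK-5099, and Acvr1b (log2 fold change -0.13, adjusted p = 0.0532) did not pass the test. Acvr1c was below the low filter at 0.715 and 0 normalized counts. Of the BMP receptors, Acvr1, Bmpr1a and Bmpr1b had log2 fold changes of 0.00, 0.08 and 0.30 and did not pass it. Bmpr1a and Bmpr1b passed it only after upper-quartile rescaling (adjusted p = 0.0247 and 0.0468, with highest values of 0.791 and 0.217 over the alternatives). Acvr1b passed it in 5 alternatives, including the fit without UK-5099 replicate 3 (adjusted p = 0.0297), in a range from 0.00341 to 0.176.

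Of 25 TGF-beta and SMAD2/3 target genes, 14 were lower and 6 higher with UK-5099, where the other group had received the receptor inhibitor (camera, adjusted p = 0.0496, and adjusted p = 0.740 with an estimated correlation). Nedd9 was 2.92-fold lower (185 ± 15.5 against 540.4 ± 16.05 normalized counts, SD, n = 3) and Smad7, the inhibitory SMAD induced by the pathway, 1.34-fold lower. Going the other way, the collagen genes Col4a1 and Col4a2 were 2.80-fold and 2.62-fold higher and Tgfbi 2.26-fold higher. The call of this list ended, with medians no nearer to 0 than -0.30 on the log2 scale against -0.34, when libraries were centred on their median (median -0.43, adjusted p = 0.0956) and in 4 of the 6 fits without a library, namely without UK-5099 replicate 1 or 2 (adjusted p = 0.0666 and 0.0690) and without 3-inhibitor replicate 1 or 3 (adjusted p = 0.0569 and 0.0713), in a range with the preset correlation from 0.0195 to 0.0956, whereas fry called it (adjusted p = 0.0136). For BMP and SMAD1/5 targets, 4 of 11 were higher and 1 lower (camera, adjusted p = 0.108). Those higher were Id1 (4.36-fold, 437.1 ± 42.9 against 100.6 ± 21.9 normalized counts), Id3 (9.90-fold, 68.2 ± 13.99 against 6.47 ± 3.48), Id2 (1.42-fold) and Fst (3.25-fold). Id1, Id2 and Id3 encode inhibitors of differentiation that BMP signals induce. The 1 lower was Id4, of the same family, chosen after its values were seen (log2 fold change -0.52 ± 0.13, adjusted p = 0.00476).

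Genes of cell shape and adhesion were also divided. Targets of YAP and TEAD were lower in 18 of 23 cases and higher in 4 (camera, adjusted p = 0.000715, and adjusted p = 0.609 with an estimated correlation), with F3, Arhgef17 and Wwc1 1.86-fold, 1.98-fold and 1.72-fold lower and the receptor tyrosine kinase gene Axl 1.63-fold higher. Epithelial junction genes were lower in 16 of 25 cases and higher in 5 (camera, adjusted p = 0.00236, and adjusted p = 0.740 with an estimated correlation). The tight junction genes Cldn3 and Cldn7 were 4.02-fold and 2.23-fold lower, whereas Cldn1 was 4.25-fold and the desmosomal gene Pkp1 1.79-fold higher. Actin and SRF target genes had 8 of 22 higher and 4 lower (camera, adjusted p = 0.304), with Cald1, Filip1l and Tpm4 higher and Zyx lower. Among 24 genes of basement membrane and integrins, 11 were higher and 9 lower (camera, adjusted p = 0.874). Lama5 was 2.86-fold and Lamb2 2.51-fold lower. Genes of epithelial-mesenchymal transition had 4 of 12 higher and 3 lower, with a median log2 fold change of -0.01 and a mean of 0.63 (camera, adjusted p = 0.520). Sparc, Tnc (5.82-fold) and Lgals1 (3.14-fold) were higher and Itgav 1.56-fold lower.

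Stress and immune genes showed both directions. NRF2 target and antioxidant genes were higher in 19 of 23 cases and lower in 3 (camera, adjusted p = 5.86e-07, and adjusted p = 0.385 with an estimated correlation). Nqo1, a quinone reductase, was 4.48-fold higher (5746 ± 320 against 1281 ± 32.9 normalized counts, SD, n = 3), the cystine transporter Slc7a11 2.74-fold, catalase (Cat) 2.70-fold and the glutathione synthesis gene Gclc 2.24-fold. Targets of ATF4 had 16 of 29 higher and 8 lower (camera, adjusted p = 0.164, or 0.0401 without the low filter, in a range from 0.0401 to 0.256 with the preset correlation; adjusted p = 0.752 with an estimated correlation and 0.0169 by fry), with Cth 1.72-fold higher and Stc2 1.61-fold lower. In the unfolded protein response 8 of 18 were lower and 3 higher (camera, adjusted p = 0.350), among them Sel1l, Calr, Derl3 and Hyou1 with log2 fold changes of -0.63, -0.67, -0.81 and -0.28. Immediate early and heat shock genes were lower in 14 of 21 cases and higher in 5 (camera, adjusted p = 0.0212, and adjusted p = 0.610 with an estimated correlation). Hspa1a and Hspa1b, near-identical copies that can share reads, were 2.86-fold and 2.97-fold lower, Dusp1 was 2.85-fold lower and Hspb1 2.65-fold higher.

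Inflammatory targets of NF-kB were lower in 15 of 25 cases and higher in 3 (camera, adjusted p = 0.00394, and adjusted p = 0.450 with an estimated correlation). Besides Cxcl5, Cxcl17 was 9.38-fold and Lcn2 8.23-fold lower, at 38.2 and 37.9 normalized counts with UK-5099, and Il1rn was 1.58-fold higher. The interferon response list had 17 of 39 higher and 6 lower (camera, adjusted p = 0.0520). It passed the threshold in 3 of the 6 fits that left out a library (adjusted p = 0.0212 without UK-5099 replicate 1, 0.0179 without 3-inhibitor replicate 1 and 0.0451 without 3-inhibitor replicate 2) after centring on the median (adjusted p = 0.0204) and without the low filter (adjusted p = 0.00331), the highest value with the preset correlation being 0.183, and by fry (adjusted p = 0.0443), but not with an estimated correlation (adjusted p = 0.752). Rsad2, Oasl1 and Ifit1, which interferon induces, were 7.27-fold, 3.37-fold and 2.81-fold higher, and H2-K1, a class I antigen-presenting gene with close copies, was 1.52-fold lower. The Notch pathway had 7 of 14 higher and 5 lower (camera, adjusted p = 0.520), with Notch1 and Notch3 1.73-fold and 1.97-fold higher and Rbpj and Dtx4 1.58-fold and 2.54-fold lower. The Wnt list, which holds ligands and receptors as well as targets, had 9 of 19 higher and 4 lower (camera, adjusted p = 0.271). Apcdd1 and Wnt10a were 3.56-fold and 2.95-fold higher and Wnt7b and Lgr4 were lower. EGFR and growth factor genes had 8 of 25 higher and 13 lower (camera, adjusted p = 0.304), including Areg (3.61-fold higher), Fgfr2 (1.73-fold higher), Dusp4 (3.25-fold lower) and Erbb3 (1.89-fold lower).

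**Figure D2:**
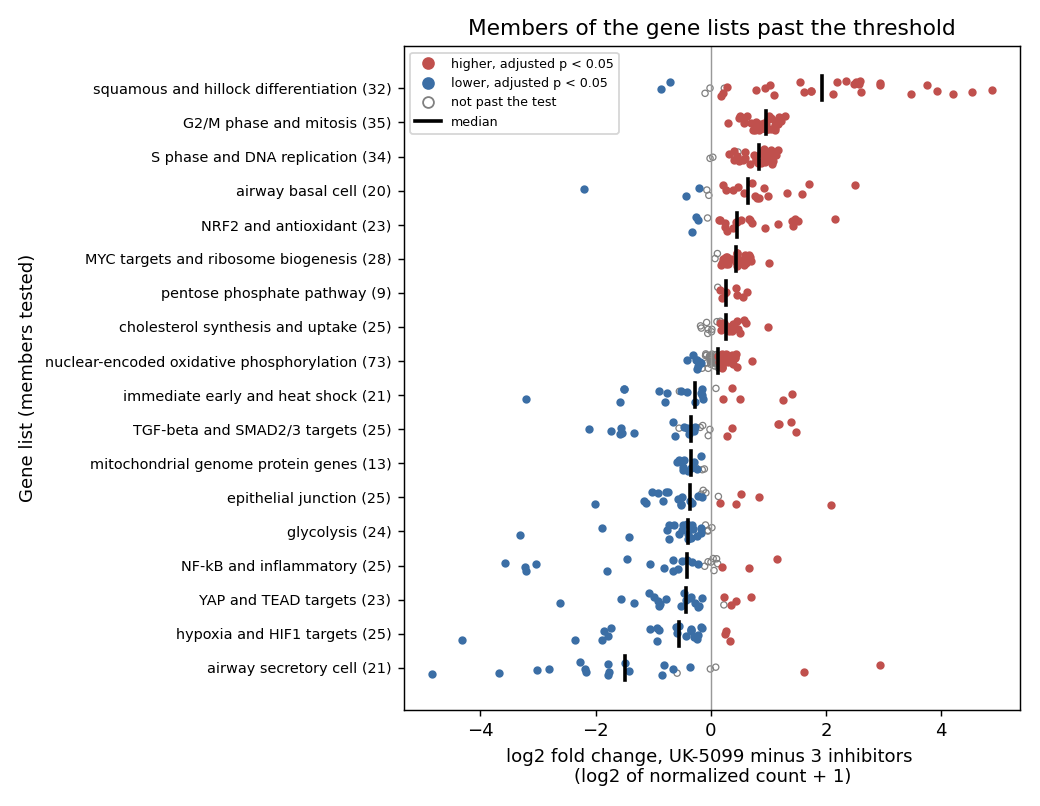
Log2 fold changes (UK-5099 minus 3 inhibitors, x axis) of the tested members of the 18 gene lists past the threshold (y axis, number tested in parentheses); each point is a gene, filled where its adjusted p was under 0.05, and black bars are list medians. List medians run from -1.49 for secretory cell genes to 1.94 for squamous and hillock genes.

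Of the 36 lists with enough tested members, 18 passed the camera test with its preset correlation, 9 higher and 9 lower, and none did with an estimated correlation, where their adjusted p ran from 0.385 to 0.752. At an unadjusted p under 0.05, 2 lists passed with an estimated correlation, and fry, which asks whether the genes of a list move on balance in one direction, called 29. Member counts adjusted over the list alone equalled those over all genes for 35 of the 44 lists. They differed for S phase (32 higher), MYC and ribosome biogenesis (27 higher), the pentose phosphate pathway (9 higher), oxidative phosphorylation (30 higher), cholesterol synthesis (1 lower), YAP (5 higher), epithelial junction (18 lower), NF-kB (4 higher) and Notch (6 lower). Some lists share members, so their calls are not independent. G6pdx, Pgd, Tkt and Taldo1 are in both the pentose phosphate and NRF2 lists. Slc2a1, Ldha, Pfkfb3 and Pfkfb4 are in both the glycolysis and HIF1 lists.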

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

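The limma-voom fits to recovered reads were chosen after the data had been seen, and the other alternatives before. The count of 8449 changed genes lay between 7516 and 8686 under other scalings, low filters, pseudocounts, trend settings and voom, and was 6648 at a threshold of 0.01. With a minimum change of 2-fold, 1593 genes passed, 733 higher and 860 lower, by the construction of that minimum. Without a replicate the count ran from 7351 to 9126 (3716 to 4596 higher, 3603 to 4530 lower). The split moved with scaling. After centring on the median, which shifted the median of all genes by -0.089 on the log2 scale, 3375 were higher and 5261 lower. There 7549 of the 8449 genes kept their call and direction. Upper-quartile rescaling shifted the median of all genes by 0.029 and moved the split the other way, to 4695 higher and 3917 lower. No called gene was called in the opposite direction in any of these fits. Of the 18 gene lists, 0 passed with an estimated correlation. Correlation between members is not the only reason. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries and not from the genes, which by itself raises p. Mitochondrial pyruvate entry, not among the 18, had an estimated correlation of -0.006, below the preset 0.01. Its adjusted p by camera still rose from 0.0924 to 0.385, though an adjusted p also depends on the other lists. By contrast, fry, which asks another question, called 29 of the 36 lists tested. Of the 18 it called 17, and not nuclear-encoded oxidative phosphorylation (adjusted p = 0.0692). Other settings gave 17 to 21 lists, and 17 to 19 without a replicate. Among 2948 values of 185 named genes under alternatives, 2920 stayed on their side of the threshold; 5 values of Acvr1 and Bmpr1a changed sign without a call in either fit, and no others did; 6 genes lost their call somewhere. The difference in mitochondrial share ran from -0.834 to -0.696 percentage points without a replicate. With the replicate number as a replicate block 8423 genes were changed. The numbers do not appear to pair the libraries: deviations from the group means correlated by -0.017, 0.116 and -0.089 across genes, which are not independent replicates, between libraries of the same number, and only UK-5099 replicate 2 correlated best with its own number. TMM scaling was not run. Depth limits genes near the low filter, where a mean of 10 normalized counts rests on about as many reads.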

Other observations

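Genes grouped into families after their values were seen, and so only described, included several that were mostly higher with UK-5099. All 7 tested kallikrein-related peptidases, proteases that shed squamous cells, were higher (median log2 fold change 1.83), among them Klk8 at 730 ± 13.03 against 166 ± 11.3 normalized counts (SD, n = 3). Of 7 desmosomal cadherins 6 were higher and 1, Dsg2, was lower (median 2.53). Dsg3 had a log2 fold change of 1.07, and Dsg1b was 32.6-fold higher. Of 7 connexins, which form gap junctions, 5 were higher and none lower (median 0.49), with Gjb6 10.2-fold and Gja1 2.72-fold higher. Of 14 B-clade serpins, protease inhibitors, 7 were higher and 2 lower (median 0.56), with Serpinb5 2.66-fold higher. Among 19 glutathione S-transferases 14 were higher and 1 lower (median 0.89), and of 14 tubulins 11 were higher and 1 lower (median 0.73). Reads can be shared among close copies within them, as for Dsg1a and Dsg1b or the Gsta genes, so single members are uncertain.

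All 3 subunits of the epithelial sodium channel, which takes up sodium from the airway surface, were lower with UK-5099: Scnn1a at 4589 ± 578 against 13990 ± 525 normalized counts, Scnn1b at 9.66 ± 1.37 against 183 ± 5.99 and Scnn1g at 35.04 ± 5.45 against 740 ± 39.0 (SD, n = 3). Of 17 potassium channel genes 6 were lower and 2 higher and 9 did not pass the test (median -0.20). Medians of these 8 families kept their direction under both other scalings. Upper-quartile rescaling and centring shifted the median of all genes by only 0.029 and -0.089 on the log2 scale. That is less than any of these family medians, so no direction could change.

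The splits of the samples, the camera tests of whole lists and the median test on shared list members were planned before their results were seen, and the other tests in the paragraphs that follow were chosen afterwards. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split was the 1 split that called 8449 genes, with 4275 higher and 4174 lower, and the highest of the other 9 was 0 in each count (limma), with 39 to 373 genes at an unadjusted p under 0.05. For gene lists the real split called 18, also the 1 split with as many, but the other 9 splits still called 10 to 16 lists. Each of these 9 sets 2 libraries of one group and 1 of the other against the reverse and so keeps part of the real contrast, which can itself give such calls. Correlation between members, with an estimated median of 0.265 over the lists against the preset 0.01, can give them too. It could inflate the 18 calls of the real split in the same way. The mixing of groups in the other 9 splits also adds the real contrast to the spread within each side. The 0 called genes there could follow from this alone and lend no support to the 8449.

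Xist was 1.70-fold higher with UK-5099 and Ddx3y, Eif2s3y, Kdm5d and Uty were lower. A difference in scaling or depth moves all genes of a library alike and is argued against by the gap of 1.37 on the log2 scale between Xist and the Y-linked gene that fell least. More female cells in the UK-5099 cultures may explain it, since 4 of the 4 Y-linked genes were lower in every UK-5099 library; with unchanged expression per cell, the Y-linked genes and Xist would need 60.9% male cells with the 3 inhibitors and 33.4% with UK-5099. Against it, X-linked genes that escape inactivation were higher in 1 of 4 cases, with a median log2 fold change of -0.14 where 0.26 would follow from a 2-fold level in female cells, so this stays open, as does a difference in expression of these genes, and the mix cannot be told apart from the treatment by design. If cells of each sex are alike and expression per cell is unchanged, a shift of the mix alone does not account for 862 genes. These called genes, 531 higher and 331 lower, lie beyond the bounds set by Xist and Kdm5d with a margin of 2 SE on either side. The other 7587 called genes do not clear that margin. Neither condition is known to hold.

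Gene families known from the earliest embryo were higher with the 3 inhibitors at low counts: Zscan4 at 163 ± 35.8 against 26.2 ± 8.74 summed normalized counts (SD, n = 3), Tcstv at 61.8 against 2.75, Zfp352 at 45.3 against 2.08, Tdpoz at 354 against 46.1, Usp17l at 159 against 38.2, numbered Eif1ad copies at 361 against 116 and Pramel at 902 against 446. Reads exchanged between copies of a family are argued against, since the sum was higher in every 3-inhibitor library for all 6 families with more than 1 gene with reads (Zfp352 has a single one). Genomic DNA or background reads are argued against as the source of most of the gain. Olfactory receptor genes, taken here as silent, were also higher in every 3-inhibitor library by sum, but by 0.66 ± 0.17 (SE) counts per gene, 3.9% of the 17.1 gained per family gene, and vomeronasal receptor genes did not gain (-0.15 ± 0.19). The bound for this test was set after a comparison of summed ratios (1.17 against 3.02) had left the question open. The families were chosen after their values were seen, which favours a higher sum and a larger gain per gene. That choice weakens the argument on copies and the one on genomic DNA. Pluripotent cells are argued against, since Pou5f1, Nanog, Zfp42, Dppa4 and Tdgf1 had 0 reads in each library. Embryonic cells without transcripts of these genes would not be seen by this test, so they remain open. A difference in expression in the cultured basal cells and reads from related transposons elsewhere also remain open and were not tested.

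Of 25 TGF-beta target genes 14 were lower and 6 higher with UK-5099 than in cells given a TGF-beta receptor inhibitor (camera, adjusted p = 0.0496, and adjusted p = 0.740 with an estimated correlation). Under the other scalings the list's median was -0.31 at its highest. Upper-quartile rescaling and centring on the median shifted the median of all genes by only 0.029 and -0.089 on the log2 scale. Neither could bring the list to 0, so this test does not decide on scaling as the cause of the direction. Centring ended the list's call (camera, adjusted p = 0.0956). Members shared with other lists as the cause of the direction are argued against, though narrowly. The 16 members in no other list had a median of -0.40 ± 0.29 (SE), 10 lower and 2 higher, beyond the bound of -0.1 set in advance by about 1 SE, and the 9 shared ones had a median of -0.04 (camera, preset correlation, unadjusted p = 0.0035 and 0.992). No margin was set in advance, and one of 2 SE would leave this open. Without an untreated group it is unknown which group moved, and no biological explanation was tested.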
